A study of Mus musculus with 6 samples.

How the data were processed

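Kidneys of 6 mice were profiled by RNA sequencing at postnatal day 35, 3 of the genotype called Pkd2-KO here and 3 of the genotype called Pkd2-miR-214-KO. Both genotypes carry floxed Pkd2 and a Cre transgene under the Pkhd1 promoter, and the second also carries a null allele of miR-214. Whole kidneys were frozen before RNA extraction, per the labels' protocols. The protocol names a stranded library kit for total RNA, while the series text speaks of polyadenylated RNA, so the selection step is not settled by the sources used here. The labels give neither the sex of the animals nor their litters, and nothing in them pairs an animal of one genotype with an animal of the other. The animals carry the numbers 867, 868 and 871 in Pkd2-KO and 864, 952 and 1164 in Pkd2-miR-214-KO. Whether these numbers reflect different cohorts or times of collection is not given, so such a difference cannot be told apart from genotype.

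The submitters' processing notes name TopHat2 2.0.12, edgeR and the genome build mm10, without their settings or order. One table of 20138 genes was used, with 1 line per gene symbol. Per the file headers it holds a log2 fold change, a mean expression as log2 CPM, the count scaled by library size, a likelihood ratio, a p-value and an adjusted p-value, all of them made by the authors. The likelihood ratio is a score on 1 degree of freedom, and its chi-square tail gave the deposited p-value of every gene with a largest difference of 6.25e-15. The deposited adjusted p-value equalled the Benjamini-Hochberg adjustment over the 20138 genes with a largest difference of 5.1e-14. Normalization factors, any filter on low counts and the counting of reads, including its use of strand, are not given in the sources used here.

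Values per library were not analysed here. The sequencing depth is therefore unknown, no mean or SD per group is given, and the spread between animals enters only through the authors' test. The planned tests on counts assumed counts per library. They gave way to the fallback fixed with them, a description of the authors' folds and adjusted p-values with no new test per gene. The direction of the fold is not stated in the headers. It was read from Mir214, the deleted gene, whose deposited log2 fold is negative, so positive values stand for higher expression in Pkd2-miR-214-KO. That gene can then not serve as an independent check of the labels. An approximate standard error (SE) was computed as the size of the log2 fold divided by the square root of its likelihood ratio, and an approximate 95% interval as 1.96 SE on either side. This approximation is poor for genes of low count, where fitted folds also depend on the prior count.

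The gene lists, the list test with its threshold, the rule for named genes and the seed site test were fixed before the data were examined. Of 31 lists, 30 were tested and the sex-chromosome genes are given as values. The planned test on log2 expression per library was replaced by its version for precomputed statistics, cameraPR of limma 3.58.1 under R 4.3.3, on the signed square root of the likelihood ratio. It was two-sided with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. The inter-gene correlation could not be estimated without values per library, so the test was repeated with 0.05 and 0.1. The percentile of each list's median among 10000 random lists matched on mean expression in 20 bins was computed as a description. On simulated statistics for the same 20138 genes, with 5 of the 30 lists shifted by 0.8 to 1.5 SD, the test found 90.6% of the shifted lists and called 0.56% of the others over 100 draws. The simulated genes were independent of each other. The rate of false calls where the genes of a list move together is therefore not given by this simulation.

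Seed sites were searched in the longest annotated 3' UTR of each protein-coding gene in GENCODE M21, on the assembly of mm10. Its symbols matched 19024 of the 20138 genes (94.5%), and 16880 of 16965 protein-coding genes (99.5%) had a 3' UTR. The log2 fold was regressed across genes on the presence of a 7-base site with log UTR length, UTR GC content and mean log2 CPM as covariates, and the site's coefficient was set against 200 shuffles of the site in a two-sided permutation test. On simulated folds for the 16880 genes, added shifts of 0.1 and 0.2 were recovered as 0.10 and 0.24, and no added shift gave -0.02. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

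The named genes were the targeted loci and Tlr4; up to 12 genes per direction with the largest fold among those with adjusted p under 0.05 and a mean of at least 1 CPM; the 5 per direction with the smallest p; and up to 4 members with the smallest p from each list. Some genes that come under this rule are not reported here. The rule's condition that the values of the groups do not overlap could not be applied. Other genes past the threshold (Cd163 comes under the rule through its list, while F13a1, Fgf23, Orm2, Cry1, Saa4 and Dbh do not), the further genes drawn in the plot of immune and clock genes, Csf3r, Cxcr2, Mmp9 and Cyp1a2 were chosen after their values were seen. Another 11 lists were added after the genes with the smallest p-values had been seen. The general macrophage, adrenal and liver-restricted genes and the liver genes named in advance were fixed before the values of these lists' members were looked at. Among the alternatives, another adjusted p threshold and a minimum fold were fixed in advance. Bonferroni adjustment, a minimum mean log2 CPM of 0, the other correlations, a rank version and the log2 fold as statistic were added after the data had been seen. Left out for want of values per library were other count models and normalizations, leaving out single animals, a covariate for sex, the estimated correlation, fry and other splits of the samples.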

Results

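Kidney RNA was compared between 2 genotypes of mice at postnatal day 35, with 3 animals in each. Pkd2-KO mice lack Pkd2 where Pkhd1-driven Cre is active, mainly in kidney tubules, and Pkd2 encodes polycystin-2, a cation channel whose loss causes cystic kidneys. Pkd2-miR-214-KO mice also carry a null allele of miR-214, a microRNA processed from a hairpin within the long noncoding RNA Dnm3os. The comparison asks which transcripts differ in Pkd2-deficient kidneys when miR-214 is missing. The gene values are fitted folds and tests of the authors, with n = 3 animals per genotype behind each, and the depth of the libraries is unknown. Positive log2 folds stand for higher expression in Pkd2-miR-214-KO, and errors are the approximate SE implied by each fold and its likelihood ratio.

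Kidneys without miR-214 had lost most reads of the Mir214 locus. Among the single genes that rose were Marco, Lyve1, Cd163 and F13a1, all expressed by macrophages, Lyve1 not by them alone, while the list of macrophage and monocyte markers did not pass. Their log2 folds in the authors' deposited table were 5.99 ± 1.01 (SE) for Marco, 2.84 ± 0.56 for Lyve1, 1.76 ± 0.35 for Cd163 and 1.45 ± 0.29 for F13a1. Marker lists of B and plasma cells, neutrophils and blood rose, with median log2 folds of 1.87, 1.60 and 1.44, and glycolysis genes rose by a median of 0.46. Lists of the cell cycle (median -0.78), the proximal tubule (-0.49), the thick ascending limb (-0.47) and antigen presentation (-0.42) fell. Beside the immune lists, genes typical of other organs had large positive folds, of which Bhmt (4.90 ± 1.16) and Dbh (5.27 ± 1.31) passed and the liver gene for albumin (Alb, 6.64 ± 2.05, adjusted p = 0.226) did not in the authors' deposited table. Xist, the RNA that silences an X chromosome in female cells, rose by 10.21 ± 2.36 in the authors' deposited table.

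The targeted loci were examined at the positions given by GENCODE M21 on the assembly of mm10. Mir214 lies on chromosome 1 from 162223368 to 162223477 on the plus strand, inside exon 1 of Dnm3os (162217623 to 162225550), which runs antisense to Dnm3 (161982453 to 162478034, minus strand). In the authors' deposited table Mir214 fell with a log2 fold of -7.62 ± 1.08 (adjusted p = 1.34e-08) at a mean log2 CPM of -1.83. Libraries of long RNA measure reads over the hairpin locus, not the mature microRNA. Dnm3os had a log2 fold of -1.23 ± 0.37 (adjusted p = 0.213), Mir199a-2, the neighbouring hairpin in the same RNA, -1.90 ± 1.26 (adjusted p = 1) and Dnm3 -0.29 ± 0.26 (adjusted p = 1) in the authors' deposited table. Reads of these overlapping genes can be told apart only where strand and position were used in counting, which the sources used here do not state. Pkd2 (chromosome 5, 104459450 to 104505819) is deleted in both genotypes, and its log2 fold in the authors' deposited table was -0.11 with an approximate 95% interval of -0.55 to 0.33.

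At an adjusted p under 0.05, 25 of the 20138 genes in the authors' deposited table differed, 21 higher and 4 lower in Pkd2-miR-214-KO. Without adjustment 970 genes (4.82%) had a p under 0.05, against 1006.9 (5%) given by chance alone, 625 of them higher and 345 lower. The genes that fell were Mir214, Cyp1a1, Prune2 and Pisd-ps1. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, changed by -3.94 ± 0.56 (adjusted p = 1.34e-08), and Prune2 by -1.19 ± 0.28 (adjusted p = 0.0168) in the authors' deposited table. Pisd-ps1 is a pseudogene, and its log2 fold of -0.97 ± 0.24 (adjusted p = 0.0430) in the authors' deposited table is uncertain because reads of its parent gene Pisd may be shared with it.

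**Figure D1:**
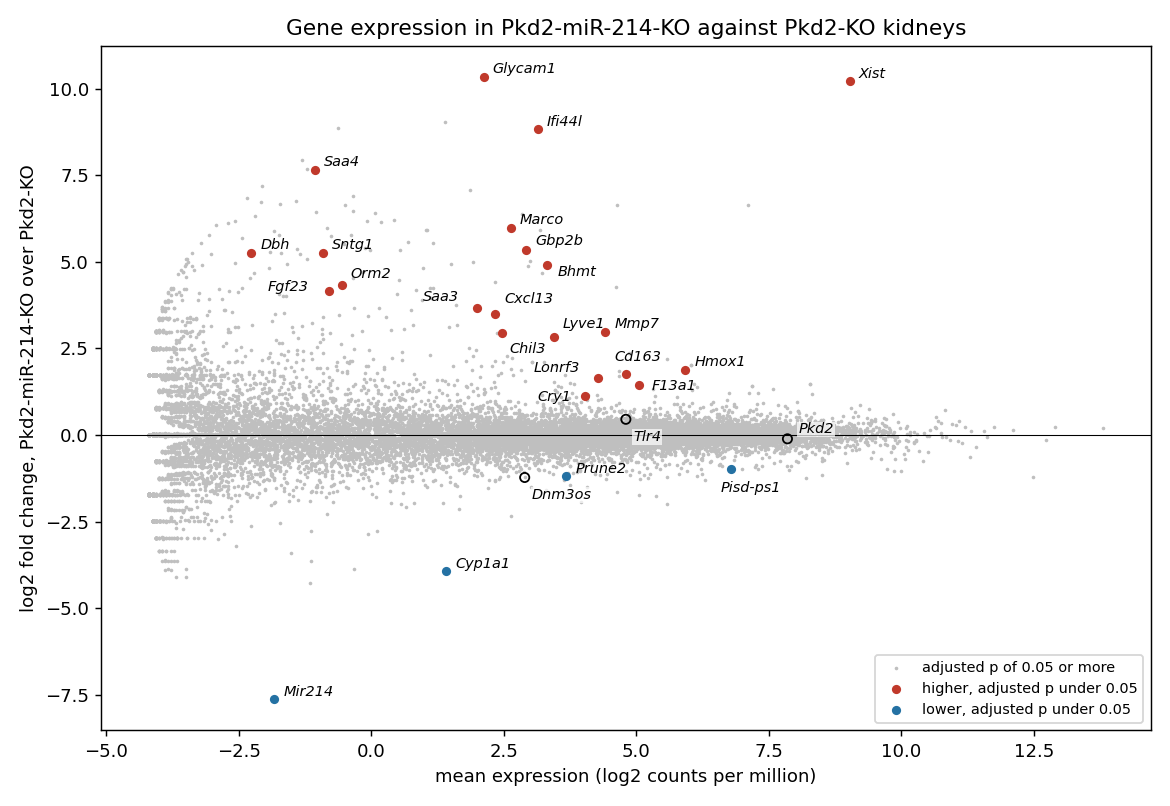
Log2 fold change of Pkd2-miR-214-KO over Pkd2-KO (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 20138 genes of the authors' deposited table. Red points are the 21 genes higher and blue points the 4 genes lower at an adjusted p under 0.05, open circles mark Dnm3os, Pkd2 and Tlr4, which did not pass, and Mir214 lies lowest at -7.62.

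Among the genes that rose, the smallest adjusted p in the authors' deposited table was that of Ifi44l, an interferon-induced gene on chromosome 3 (151758737 to 151762892), with a log2 fold of 8.82 ± 0.86 (adjusted p = 1.63e-20). Gbp2b, a guanylate-binding protein gene on the same chromosome (142594847 to 142619179), rose by 5.34 ± 1.06 in the authors' deposited table, a value made uncertain by reads that its close paralogs can share. Sntg1, a syntrophin gene, had a log2 fold of 5.26 ± 0.81 (adjusted p = 5.32e-07) at a low mean log2 CPM of -0.91 in the authors' deposited table. Cxcl13, a chemokine that attracts B cells, rose by 3.49 ± 0.66, Chil3, a chitinase-like protein of activated macrophages, by 2.94 ± 0.67, and Saa3, an acute-phase protein, by 3.66 ± 0.84 in the authors' deposited table. Hmox1, the enzyme that degrades heme, rose by 1.87 ± 0.39, Mmp7, a matrix metalloproteinase of injured tubules, by 2.98 ± 0.62, and Lonrf3 by 1.66 ± 0.32 in the authors' deposited table. Fgf23, a phosphate-regulating hormone, rose by 4.15 ± 0.86, Orm2, an acute-phase gene with close paralogs, by 4.32 ± 0.95, and the clock gene Cry1 by 1.14 ± 0.27 in the authors' deposited table. The remaining genes that rose were Xist, Glycam1 (10.33 ± 2.50), Saa4 (7.66 ± 1.87), Dbh (5.27 ± 1.31), which encodes the enzyme that makes noradrenaline, and Bhmt (4.90 ± 1.16), a methyltransferase abundant in liver, each with an adjusted p between 0.0168 and 0.0475 in the authors' deposited table. Among genes of similar expression in the authors' deposited table, the approximate SE lay at the 99.9 percentile for Glycam1 and at the 99.6 percentile for Xist.

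Macrophage genes did not move as a group. In the list of 23 macrophage and monocyte markers, 12 log2 folds were positive and 11 negative, with a median of 0.02 (adjusted p = 0.320, cameraPR). Cd163, a scavenger receptor for hemoglobin, was the 1 member past the threshold over all genes and also 1 when adjusted over the list alone. In the authors' deposited table Mrc1, the mannose receptor, had a log2 fold of 0.51 ± 0.24, Itgax -0.75 ± 0.37 and Emr1, which encodes the F4/80 antigen, -0.37 ± 0.27, and none of these passed. Marco and Lyve1, a scavenger receptor and a hyaluronan receptor, are also expressed outside the kidney, Marco by macrophages of the liver and spleen. The liver macrophage gene Clec4f had a log2 fold of 6.17 ± 2.05 (adjusted p = 0.325) in the authors' deposited table, beside the 6.64 of Alb.

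B and plasma cell markers rose (adjusted p = 3.21e-15, cameraPR), with positive folds for 10 of 10 genes, 0 past the threshold over all genes and 7 adjusted over the list alone. In the authors' deposited table Ms4a1, which encodes CD20, had a log2 fold of 4.23 ± 1.14, Cd79a 3.77 ± 1.11 and Pou2af1 3.19 ± 0.94. Neutrophil markers rose as well (adjusted p = 7.35e-09), with 9 of 10 folds positive, 0 genes past the threshold over all genes and 7 adjusted over the list alone. The members outside those 7 were Csf3r (-0.16 ± 0.32), Cxcr2 (0.11 ± 0.45) and Mmp9 (0.47 ± 0.54) in the authors' deposited table. The granule protein genes Ngp (6.63 ± 1.75, mean log2 CPM -0.48), Camp (5.24 ± 1.75, mean log2 CPM -1.69), Ltf (1.63 ± 0.58) and Mmp8 (1.61 ± 0.59) carried the list's smallest p-values in the authors' deposited table. Blood genes rose beside them (adjusted p = 2.26e-06), with 8 of 8 folds positive and 0 past the threshold, both over all genes and adjusted over the list alone. Among these the erythroid genes Hbb-bt (2.03 ± 0.87) and Alas2 (1.84 ± 0.86) had an adjusted p of 0.772 or more in the authors' deposited table. The median approximate SE of the B cell list lay at the 95.1 percentile, and that of the blood list at the 99.6 percentile, of genes of similar expression.

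T and NK cell markers fell (median -0.36, 14 of 16 negative, adjusted p = 0.00379), with 0 genes past the threshold over all genes or adjusted over the list alone, a call lost with a correlation of 0.1 (adjusted p = 0.0909) and with a minimum mean log2 CPM of 0 (adjusted p = 0.0531). The granzyme genes Gzmb (-1.92 ± 0.81) and Gzma (-1.78 ± 0.97) had the smallest p-values among them in the authors' deposited table. The antigen presentation list fell (12 of 14 negative, adjusted p = 2.84e-06), with 0 genes past the threshold over all genes and 3 adjusted over the list alone. Its MHC class II genes H2-Eb1 (-0.93 ± 0.31), H2-Ab1 (-0.86 ± 0.31), Cd74 (-0.80 ± 0.31) and H2-Aa (-0.75 ± 0.31) had the smallest p-values of the list in the authors' deposited table. The interferon list fell (median -0.19, 24 of 30 negative, adjusted p = 0.0166), with 0 genes past the threshold over all genes or adjusted over the list alone, against the rise of Ifi44l and Gbp2b, which are not among its members. That call was lost with a correlation of 0.05 (adjusted p = 0.114) and with the log2 fold as statistic (adjusted p = 0.363). Ifi44 (0.60 ± 0.26), Bst2 (-0.63 ± 0.33) and Ifngr1 (0.41 ± 0.22) were among its members with the smallest p-values in the authors' deposited table.

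**Figure D2:**
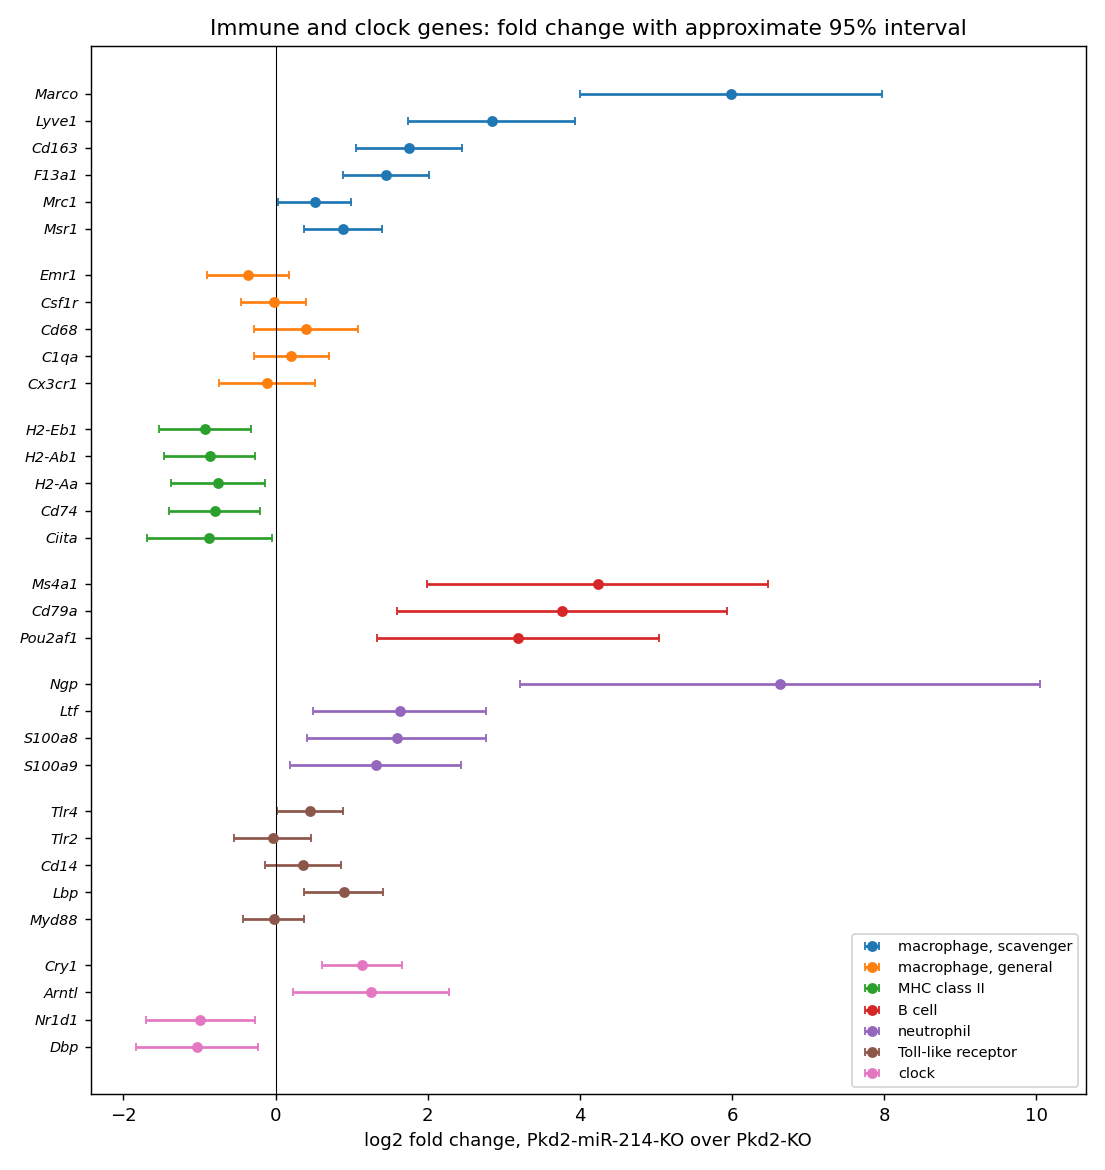
Log2 fold change of Pkd2-miR-214-KO over Pkd2-KO (horizontal axis) for single genes of 7 groups (colours) in the authors' deposited table, with bars for the approximate 95% interval. Of the 6 scavenger macrophage genes drawn, Marco, Lyve1, Cd163 and F13a1 passed an adjusted p of 0.05 over all genes, as did Cry1 among the clock genes, while the MHC class II genes lie below 0 and the general macrophage genes span it.

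Tlr4, the endotoxin receptor, has been proposed as a target of miR-214. Its log2 fold in the authors' deposited table was 0.45 with an approximate 95% interval of 0.02 to 0.89 (adjusted p = 0.989). Its longest annotated 3' UTR of 1324 bases holds 0 copies of the 7-base miR-214-3p site. Shorter or shifted matches, other transcripts and the coding sequence were not searched, so this does not show that Tlr4 lacks a site. Toll-like receptor and NF-kB genes had a median of 0.06 (18 of 28 positive, adjusted p = 0.129), with 0 genes past the threshold over all genes and 1 adjusted over the list alone, the endotoxin-binding protein gene Lbp (0.90 ± 0.26, adjusted p = 0.202 in the authors' deposited table). Cytokine and chemokine genes had a median of -0.09 (11 of 29 positive, adjusted p = 0.557), with 0 past the threshold over all genes and 1 adjusted over the list alone, Ccl6 (0.77 ± 0.23 in the authors' deposited table). Ccl9 (0.81 ± 0.30), Cxcl10 (-0.81 ± 0.39) and Cxcl9 (-1.53 ± 0.78) moved in both directions without passing in the authors' deposited table. Complement genes rose (median 0.22, 11 of 16 positive, adjusted p = 0.0239), with 0 past the threshold over all genes or adjusted over the list alone, and Cd55, an inhibitor of complement, had the smallest p-value among them with a log2 fold of 0.72 ± 0.28 in the authors' deposited table. The complement call was lost with a correlation of 0.05 (adjusted p = 0.0973) and with the log2 fold as statistic (adjusted p = 0.720). Literature targets of miR-214 had a median of 0.07 (15 of 20 positive, adjusted p = 0.299) and 0 genes past either threshold, over all genes or adjusted over the list alone.

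Tubule lists were tested by segment, each against all other genes. Proximal tubule markers fell (21 of 22 negative, adjusted p = 2.13e-07), with 0 genes past the threshold over all genes and 1 adjusted over the list alone, the urate transporter gene Slc22a12 (-1.24 ± 0.38 in the authors' deposited table). The phosphate transporter gene Slc34a3 (-1.16 ± 0.42), Gatm (-0.99 ± 0.47) and Slc7a13 (3.99-fold lower) followed without passing in the authors' deposited table, and Slc7a13 is also a male-biased kidney gene. Thick ascending limb markers fell (9 of 10 negative, adjusted p = 1.30e-05), with 0 genes past the threshold over all genes or adjusted over the list alone and log2 folds of -1.05 ± 0.45 for Egf, -0.99 ± 0.38 for Ppp1r1a and -0.58 ± 0.23 for Cldn19 in the authors' deposited table. Distal convoluted tubule (median -0.01, adjusted p = 0.768), principal cell (0.08, adjusted p = 0.445), intercalated cell (0.23, adjusted p = 0.0795) and podocyte markers (-0.09, adjusted p = 0.274) did not pass. None of these 4 lists had a gene past the threshold over all genes, and adjusted over the list alone 1 passed, the proton pump gene Atp6v0d2 (0.82 ± 0.26 in the authors' deposited table). Genes of tubular injury and cyst epithelium rose slightly (median 0.13, 16 of 21 positive, adjusted p = 0.0425), with 0 past the threshold over all genes or adjusted over the list alone, a call lost with a correlation of 0.05 (adjusted p = 0.145) and with the log2 fold as statistic (adjusted p = 0.745). Among its injury genes the signs differed, with -1.18 ± 0.43 for Havcr1, which encodes KIM-1, and 0.75 ± 0.39 for Lcn2 in the authors' deposited table.

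Cell cycle genes fell as a list (26 of 26 negative, adjusted p = 7.35e-09) with 0 past the threshold over all genes or adjusted over the list alone. Without adjustment, too, 0 of the 26 had a p under 0.05. The median approximate SE of the list lay at the 94.8 percentile of genes of similar expression, and that of the proximal tubule list at the 93.6 percentile. Plk1 (-1.08 ± 0.55), Tk1 (-0.91 ± 0.47), Birc5 (-0.96 ± 0.61) and Mcm5 (-0.69 ± 0.41) had the smallest p-values of the cell cycle list in the authors' deposited table. Glycolysis genes rose (15 of 16 positive, adjusted p = 4.50e-06), with 0 past the threshold over all genes or adjusted over the list alone, and the glucose transporter gene Slc2a1 (0.82 ± 0.29) and the lactate exporter gene Slc16a3 (1.31 ± 0.50) had its smallest p-values in the authors' deposited table. Oxidative phosphorylation genes fell slightly (median -0.15, 24 of 25 negative, adjusted p = 0.0425), as did polycystic and cilia disease genes (median -0.15, 21 of 28 negative, adjusted p = 0.0411) and endothelial markers (median -0.20, 12 of 14 negative, adjusted p = 0.0166). All 3 calls were lost with a correlation of 0.05 (adjusted p = 0.145, adjusted p = 0.145 and adjusted p = 0.0696) and with the log2 fold as statistic (adjusted p = 0.656 for each). None of these 3 lists had a gene past the threshold over all genes or adjusted over the list alone. Fatty acid oxidation (median -0.10, adjusted p = 0.314) and immediate early genes (0.22, adjusted p = 0.0518) did not pass and had 0 genes past the threshold over all genes or adjusted over the list alone. The immediate early list passed upward with the rank version of cameraPR (adjusted p = 0.0200) and with a minimum mean log2 CPM of 0 (adjusted p = 0.0243). It did not with a correlation of 0.05 (adjusted p = 0.145) or with the log2 fold as statistic (adjusted p = 0.713).

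Collagen and matrix genes (median -0.12, 21 of 29 negative, adjusted p = 0.0799) and fibroblast and pericyte markers (median -0.21, 10 of 14 negative, adjusted p = 0.557) did not pass as lists. The collagen and matrix list passed downward with the rank version of cameraPR (adjusted p = 0.0286) and with no other setting. Mmp7 was the 1 matrix gene past the threshold over all genes and also when adjusted over the list alone. The proteoglycan gene Dcn (1.18 ± 0.31) was the 1 fibroblast gene adjusted over the list alone, with 0 over all genes, and Lum had 1.21 ± 0.47 in the authors' deposited table. Markers of adipose, adrenal, muscle and urothelial tissue had a median of -0.15, a mean of 0.23 and a test direction upward (adjusted p = 0.449), with 0 genes past the threshold over all genes or adjusted over the list alone. The adrenal genes Cyp11b1 (2.37 ± 1.61), Cyp21a1 (2.10 ± 1.16) and Cyp11a1 (1.98 ± 1.10) stood highest in it in the authors' deposited table.

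Among the sex-chromosome genes Xist was the 1 past the threshold over all genes and adjusted over the list alone. The Y-linked genes Kdm5d (-0.66 ± 1.40), Uty (-0.39 ± 1.66) and Ddx3y (-0.23 ± 1.54) had wide errors and did not pass in the authors' deposited table. Male-biased kidney genes had a median of -0.82 (5 of 6 negative, adjusted p = 0.0795) and female-biased ones of -0.51 (3 of 4 negative, adjusted p = 0.146), with 0 past the threshold over all genes or adjusted over the list alone in either list.

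**Figure D3:**
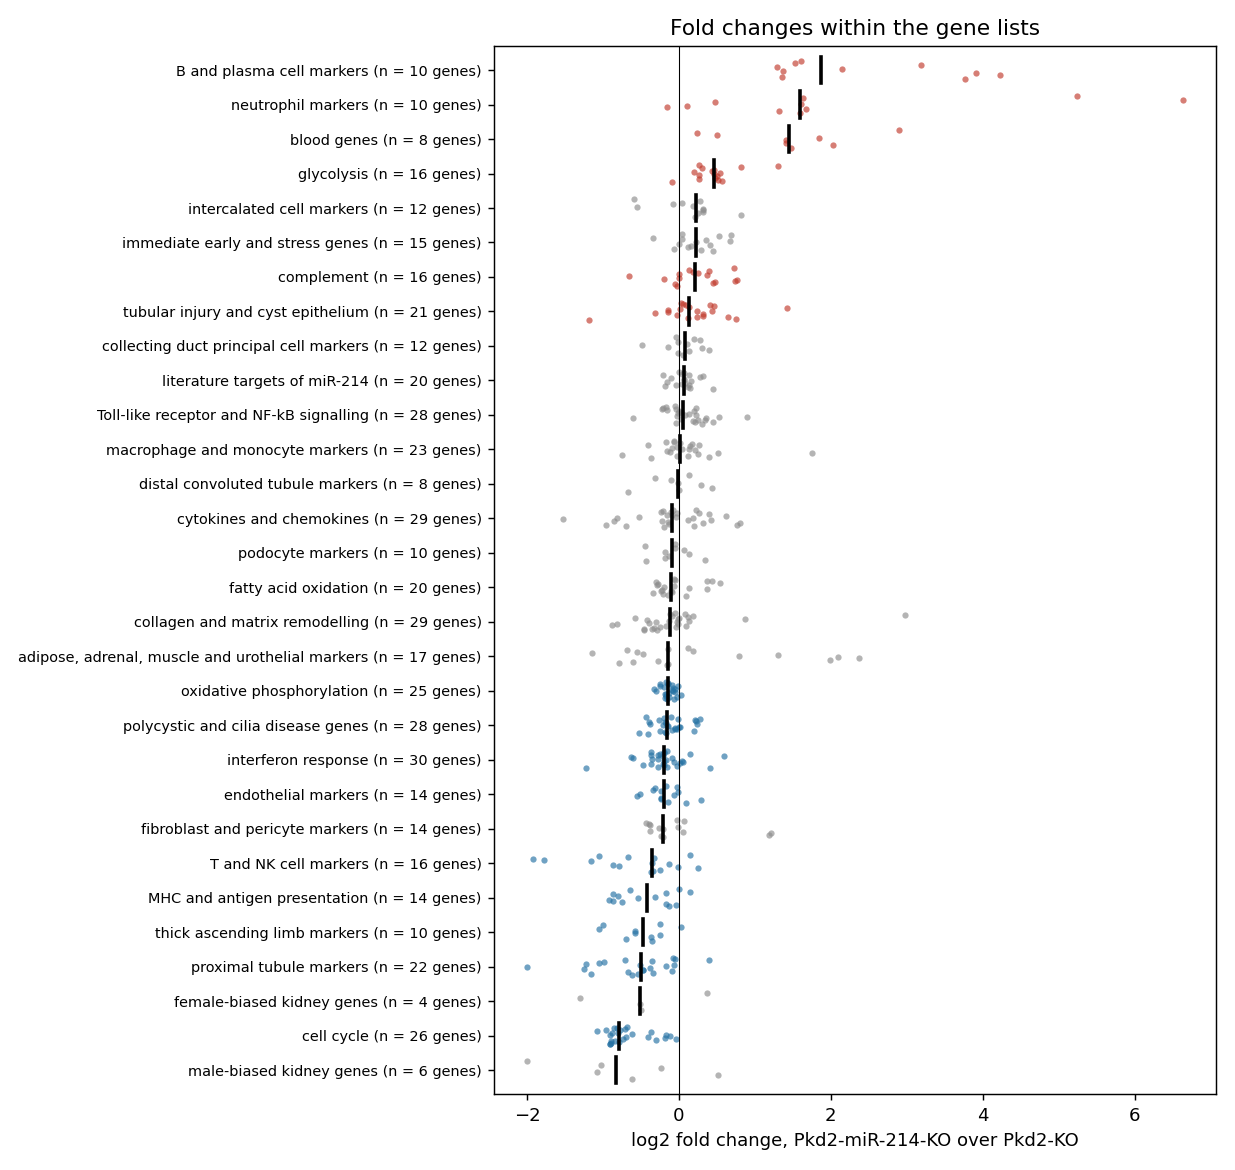
Log2 fold change of Pkd2-miR-214-KO over Pkd2-KO (horizontal axis) for every measured member (points) of the 30 tested lists, with the list median as a black bar and the number of genes beside each name. Red lists rose and blue lists fell at an adjusted p under 0.05 by cameraPR, grey lists did not pass, and medians run from -0.82 in male-biased genes to 1.87 in B and plasma cell markers.

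Of the 30 lists, 15 passed with the preset correlation of 0.01, 6 upward and 9 downward. With a correlation of 0.1 the calls held for 8 of them, namely B and plasma cell, neutrophil, blood, glycolysis, cell cycle, proximal tubule, thick ascending limb and antigen presentation. With the log2 fold as statistic 3 of the 8 calls that held at 0.1 were lost, with adjusted p = 0.129 for antigen presentation and for the thick ascending limb and adjusted p = 0.218 for glycolysis. The correlation between the genes of a list was not estimated here and could be higher than any of these settings. Genes of a list are not independent replicates, so the p-values of the list tests do not cover the spread between animals.

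Targets of the deleted microRNA were also examined by sequence. A 3' UTR match to positions 2 to 8 of miR-214-3p (CCTGCTG) was found in 3598 of 16880 genes. Their log2 folds differed from those of the other genes by -0.01 ± 0.02 (SE across genes), inside the range of -0.07 to 0.07 spanned by 95% of shuffled sites (permutation p = 0.766). Genes are not independent replicates, so that SE does not cover the spread between animals. Sites of miR-199a-3p and miR-199a-5p, made from the same host RNA, gave 0.02 (permutation p = 0.343) and 0.04 (permutation p = 0.244), and the Benjamini-Hochberg adjustment over the 3 sites leaves none of them under 0.05.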

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

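All settings named here other than the looser threshold, the minimum fold and the 8-base site were chosen after the results were seen. The count of 25 changed genes became 28 at an adjusted p under 0.1, stayed at 25 with a minimum fold of 1.5 and became 19 among genes with a mean log2 CPM of at least 0. Bonferroni adjustment left 14, 12 higher and 2 lower, all shared with the 25, since it is stricter by construction. Of the single genes tested, 19 kept their side of the threshold under Bonferroni and 11 lost it. With the minimum expression, 23 of 23 with enough expression kept it. The single genes include Pkd2, Dnm3os, Dnm3, Mir199a-2 and Tlr4, which had not passed. Under the stricter Bonferroni adjustment these could only stay uncalled, so the 14 of the 25 that remained are the informative count. The number of lists past the threshold fell from 15 to 9 and 8 with correlations of 0.05 and 0.1, because a higher correlation widens the test's error, and to 6 with the log2 fold as statistic, for which the cause was not tested. It was 17 with the rank version and 15 with the minimum expression, which shared 15 and 14 lists with the result reported, and no call turned its direction. The seed site difference of -0.01 became 0.00 with an 8-base match (permutation p = 0.945) and -0.01 with the minimum expression (permutation p = 0.652). Without values per library, DESeq2, voom and quasi-likelihood fits, other normalizations and count filters, leaving out single animals, the subset of animals with neighbouring numbers, a covariate for Xist, fry, the estimated correlation and other splits of the samples were not run, so no result has been checked against the influence of 1 animal. No paired analysis was possible because nothing in the labels pairs the animals. The unknown depth leaves open how many reads lie behind genes such as Mir214, Dbh and Fgf23, whose mean log2 CPM in the authors' deposited table is below 0.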

Other observations

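The tests of the clock genes, of the interferon list, of the errors of the Y-linked genes and of the liver enzymes were chosen after the results were seen. The 11 lists added here were written after the genes with the smallest p-values had been seen. Those of general macrophage, adrenal and liver-restricted genes and of liver genes named in advance were fixed before their members' values were looked at, and some members' values of the others were known, so that these describe the data and are no independent evidence. Genes induced by low oxygen were mostly higher, with 17 of 19 log2 folds positive and a median of 0.52. Of these, 0 were past the threshold over all genes and 7 when adjusted over the list. Overlap with the glycolysis list was not counted, so the rise of both lists is not separate evidence. In the authors' deposited table Adm, a vasodilator peptide, had a log2 fold of 1.47 ± 0.47, Egln3, an oxygen sensor, 1.33 ± 0.40, and Bnip3, a mitophagy receptor, 1.21 ± 0.41. Acute-phase genes had positive folds for 14 of 14 members, with a median of 1.62 and Saa3 and Orm2 past the threshold over all genes, and 4 of the 14 are also among the liver genes named in advance. Cyp1a1 was the only gene past the threshold among 5 targets of the aryl hydrocarbon receptor, of which 4 had negative folds, and Cyp1b1 (-0.02 ± 0.28), Nqo1 (-0.18 ± 0.29), Ahrr (-0.95 ± 0.52) and Tiparp (0.34 ± 0.23) did not pass in the authors' deposited table. Cyp1a2, the neighbouring gene of Cyp1a1 on chromosome 9 and abundant in liver, had a log2 fold of 6.76 ± 2.10 (adjusted p = 0.232) in the authors' deposited table.

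Clock genes of the morning phase had mostly higher folds than those of the evening phase. Of the 6 morning-phase genes, 1 (Cry1) passed over all genes and 4 adjusted over the list. Of the evening-phase genes, 0 of 10 passed over all genes or adjusted over the list. In the authors' deposited table Arntl had a log2 fold of 1.25 ± 0.52 and Nfil3 0.85 ± 0.38 beside Cry1, against -1.03 ± 0.41 for Dbp and -0.99 ± 0.36 for Nr1d1. With the morning-phase members whose values had been seen left out, the median of 4 morning-phase genes (1.02) exceeded that of 10 evening-phase genes (-0.13) by 1.15, most of it from the morning phase, consistent with a difference in the hour of collection or in the clock itself, which the design does not separate.

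Resident scavenger macrophage genes had positive folds for 13 of 13 members with a median of 1.81. The size of that median is uncertain because only 6 of these genes had an implied level of at least 1 CPM in Pkd2-KO. It is uncertain also because 4 were known to have passed. The median of 12 general macrophage genes was 0.0276, which argues against more macrophages of every kind. All 12 also belong to the list of macrophage and monocyte markers above, so their median is no separate evidence. Within 10 Mb of Mir214, 17 of 190 genes (8.95%) had a p under 0.05 against 861 of 17889 (4.81%) on other chromosomes, a ratio of 1.86 (one-sided Fisher's exact p = 0.0113), which became 1.67 (one-sided Fisher's exact p = 0.0387) without Mir214, Mir199a-2 and Dnm3os.

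Xist had a log2 fold of 10.21 ± 2.36 at a mean log2 CPM of 9.02 in the authors' deposited table. As Xist is an RNA of female cells, this fold argues against the same sex composition in both genotypes. It points to females among the Pkd2-miR-214-KO animals, whose number stays unknown, and to little Xist in Pkd2-KO. The 4 Y-linked genes had a median of -0.31 and a range of -0.66 to -0.14. That median alone neither excludes nor establishes a difference in the sex composition of the groups. A single group with 1 female among 3 animals would give -0.58, and the approximate SE of these Y-linked genes is 1.40 to 1.66. Their SE lay at the 99.8 percentile or above among genes of similar expression, consistent with both sexes within the Pkd2-miR-214-KO group. Whether sex accounts for part of the genes past the threshold cannot be told apart from genotype, because male-biased kidney genes (median -0.82) and female-biased ones (-0.51) both had negative medians, and a lower share of males would account for the former alone. The same limit holds for the fall of the proximal tubule list, which shares Slc7a13 with the short list of male-biased genes. The other proximal tubule genes were not examined for sex bias and may carry it too. The effect of miR-214 loss within one sex stays untested.

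Genes of other organs had large folds with large errors, such as Alb (6.64 ± 2.05, mean log2 CPM 7.11), Ahsg (6.64 ± 1.98), Apoa1 (5.92 ± 1.63) and Cyp3a11 (6.42 ± 2.21) in the authors' deposited table. An acute-phase response of the kidney is argued against as the whole source by the median of 4.82 over 11 metabolic enzymes of the liver. Of these, 10 were positive and all 11 are also liver-restricted genes below. The size of that median is uncertain, as only 3 had an implied level of at least 1 CPM in Pkd2-KO. A whole lymph node is argued against by the median of -0.36 for T and NK cell markers, beside 1.87 for B cells. That fall was lost with some settings. Glycam1 (10.33) and Cxcl13 (3.49) rose and lie outside both lists, so lymphoid tissue with few T cells stays untested. Adrenal tissue in some libraries is consistent with the median of 2.04 over 8 adrenal genes, of which 4 are also in a list fixed in advance and 1 had an implied level of at least 1 CPM in Pkd2-KO. Liver tissue in some libraries was not decided by the bounds set for and against it. The medians of 1.81 over 25 liver-restricted genes and of 1.47 over 13 liver genes named in advance lay between them. Of these genes 22 and 13 were positive, with upper quartiles of 5.08 and 4.08. In Pkd2-KO 8 and 10 of them had an implied level of at least 1 CPM. Genes already present there rise less with added liver RNA, so the medians cannot decide the question. Liver RNA may therefore contribute to Marco, Lyve1, Cd163, the neutrophil and the blood genes. Marrow RNA as a source of the B cell, neutrophil and blood genes was not tested. A response to miR-214 loss was not tested against either.

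Ifi44l (8.82 ± 0.86) and Gbp2b (5.34 ± 1.06) rose in the authors' deposited table while the interferon list had a median of -0.19 with 24 of 30 genes negative, which argues against a rise of the interferon response. Both lie on chromosome 3. Within 10 Mb of either gene, 11 of 129 others (8.53%) had a p under 0.05 against 878 of 18070 (4.86%) on other chromosomes, a ratio of 1.75 (one-sided Fisher's exact p = 0.0511). Ifi44, whose value had been seen, was left out of that count. A difference in genetic background on chromosome 3 may thus contribute but cannot be told apart from an effect of miR-214 loss at this number of genes.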
